A study of Homo sapiens with 6 samples.

How the data were processed

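RNA-seq was run on 6 libraries of HepG2, an established human hepatocellular carcinoma cell line. In 3 libraries the cells had been given free fatty acid (FFA) for 48 h, and in 3 libraries FFA together with trimethylamine N-oxide (TMAO) for 48 h. Total RNA was isolated with TRIzol, checked on a NanoDrop and a Bioanalyzer, and made into libraries with a VAHTS Universal V6 kit, per the labels' protocols.

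The values analysed are the FPKM (fragments per kilobase of gene and 1e6 mapped fragments) that the authors deposited, 1 table with 16466 gene symbols and a column for each library. HTSeq and R 3.2.0 are named for this step, per the submitters' processing notes. The same notes name mm10, a mouse genome build, whereas the labels give a human line and 16293 of the symbols are current human symbols. Another 106 matched an older human symbol and 67 matched none. The aligner, the gene annotation, the strand setting, the handling of reads that fit several places and any filter are not given in the sources used here. Since the build named differs from the reference used here, no genome coordinates are printed. Columns were assigned by name: the columns numbered 1 to 3 whose names stand for fatty liver cells were taken as FFA replicates 1 to 3, and those named for TMAO as FFA+TMAO replicates 1 to 3. That reading of the first name rests on the series' description of the control cells and on the absence of any other group. Sample groups came from the sample titles.

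FPKM are not counts, so no count model was used. The number of fragments behind them was estimated from the low values, where a gene's FPKM moves in steps of 1 fragment. Among 3888 low genes, 2070 (53.24%) had values that were whole multiples of a common step within a tolerance of 0.02. Their steps, set against exon lengths of GENCODE release 29, gave a depth of about 33.6 M (1e6) fragments (quartiles over genes 26.5 and 38.3 M). The libraries' relative depths differed by at most 1.03 times. A count of 321 genes is listed at 0 in every library. Some genes usually well expressed in HepG2 (INSIG1, ME1, IRS2 and COL4A1, chosen after their values were seen) are listed near 0 in all libraries and fell under the filter. Whether an upstream step lost their reads cannot be told from the values, so the lists they belong to may be measured in part only.

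Genes with a mean of at least 1 FPKM over the 6 libraries were tested (10305 genes). FPKM were transformed to log2(FPKM + 1), so fold changes are on that scale and understate the change of genes near 1 FPKM. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend, two-sided), without covariates, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Intervals are 95% intervals of the moderated test, with 9.07 residual plus prior degrees of freedom. Tables were prepared with Python 3.11.15 and pandas 2.3.3. The procedure was tested on simulated data with the measured means and spreads of these 10305 genes, independent between genes, in 5 runs. It recovered 36.4% of 335 genes changed 1.5-fold, 73.1% of 335 changed 2-fold and 94.8% of 330 changed 4-fold, summed over the runs. Of its calls, 4.76% were false. The measured genes are not independent, since the first principal component held 61.1% of the variance. These rates therefore need not hold for the measured libraries.

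Before the data were examined, 34 gene lists were fixed, covering lipid handling, choline and osmolyte genes, stress, inflammation, energy metabolism, the cell cycle, hepatocyte identity and markers of other liver cell types. Cytosolic ribosomal proteins, immediate early genes and replication-dependent histones were fixed as checks of RNA quality. The 30 lists with at least 3 tested members were compared with the other genes by camera with a preset correlation between genes of 0.01, then by camera with an estimated correlation and by fry, which asks whether a list's own genes move on balance in a single direction. Camera with an estimated correlation takes its p from the few residual degrees of freedom of these libraries. A list that fails it is therefore not shown to be unchanged. The other 4 lists had fewer than 3 members past the expression filter and were not tested with it: flavin monooxygenases (FMO5 alone passed the filter), the mitochondrially encoded respiratory chain (not analysed here), and the endothelial and the stellate cell and fibroblast markers, whose levels are given in the text. Without the filter the endothelial markers did not pass (adjusted p = 0.580), and the stellate cell and fibroblast markers passed in the lower direction (median log2 fold change -0.02, adjusted p = 0.0278, and p = 0.751 with an estimated correlation). Members past the threshold were also counted after adjustment over the list alone.

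Named genes followed a rule fixed at the same time: the genes past the threshold with the largest changes, or, where a direction had too few, those with the smallest unadjusted p up to 5 in that direction, given as not past the threshold. Up to 4 tested members with the smallest unadjusted p were named for each list described. ALB, FASN, SCD, CPT1A, PLIN2, APOB, EIF2AK3, DDIT3 and CYP7A1 were named in every case. Some other genes that the rule would name are not reported here. The mitochondrially encoded genes were not analysed here.

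The alternatives were pseudocounts of 0.1 and 0.5, no filter and a filter at 5 FPKM, scaling to a common sum (TPM), median-of-ratios size factors, quantile normalization, no trend, robust eBayes, array weights, the replicate number as a block, each library left out in turn, and thresholds with a fold minimum. Alternatives chosen after seeing the data were a correction of each library for GC content and transcript length (a loess fit with a span of 0.5), the first residual component as a covariate, and array weights estimated gene by gene. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical in part. With 3 samples against 3, the smallest exact permutation p of a single value is 0.1.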

Results

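Expression was compared in HepG2 cells, a human liver carcinoma line used as a model of the hepatocyte, after 48 h with free fatty acid (FFA) or with FFA plus trimethylamine N-oxide (TMAO). FFA loads such cells with lipid, and TMAO is an amine oxide that the liver makes from a product of gut bacteria. Both groups received FFA and each had 3 libraries, so the comparison asks what TMAO adds to lipid-loaded cells. Cells without FFA were not analysed here. The libraries held about 33.0 to 34.0 M (1e6) fragments each by estimate, and 10223 to 10361 genes reached 1 FPKM. Values below are mean FPKM ± SD with n = 3 in each group, and log2 fold changes are FFA+TMAO minus FFA.

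The libraries carried the hepatocyte program in both groups. ALB, serum albumin, stood at 11158 ± 770 FPKM with FFA and 10851 ± 1266 with TMAO added, a log2 fold change of -0.04 ± 0.14 (SE). AHSG, a secreted glycoprotein of the liver, stood at 4510 ± 552 and 3924 ± 733, TF (transferrin) at 446 ± 36.4 and 420 ± 7.74, and TTR (transthyretin) at 414 ± 55.3 and 484 ± 153. ARG1, the urea cycle arginase, was low, at 6.91 ± 1.16 and 5.70 ± 3.03. Of the 20 tested hepatocyte identity genes, 10 had higher and 10 lower values with TMAO, and the list did not pass (adjusted p = 0.584, camera). Its median log2 fold change of 0.0050 differed in sign from its mean of -0.01. The list lay lower with TMAO once FFA+TMAO replicate 2 was left out, with a median of -0.09 (adjusted p = 0.00108, and p = 0.472 with an estimated correlation).

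Endothelial, immune, and stellate cell and fibroblast markers were mostly low, whereas cholangiocyte markers were not. Of 9 cholangiocyte markers, 5 reached a mean of 1 FPKM over the 6 libraries, with a median of 4.175 and a highest mean of 191.5 FPKM. The 6 endothelial markers in the table had means over the 6 libraries of at most 0.197 FPKM, and the 10 stellate cell and fibroblast markers had a median of 0.0128 FPKM. Of these 10, the smooth muscle actin gene ACTA2 (31.5 ± 3.06 and 30.9 ± 1.03 FPKM) and the growth factor receptor gene PDGFRB (2.24 ± 0.119 and 1.68 ± 0.192) alone reached 1 FPKM. The immune markers that could be tested, 3 in number, included CD68 (20.5 ± 2.17 and 19.4 ± 4.09 FPKM) and LYZ, lysozyme (2275 ± 113 and 2137 ± 286). These 3 genes passed as a list in the lower direction, with a median log2 fold change of -0.10 (adjusted p = 0.0329, and p = 0.688 with an estimated correlation). The call ended without FFA+TMAO replicate 2 (median 0.02, adjusted p = 0.566), and also without FFA replicate 1 (adjusted p = 0.254), FFA replicate 2 (0.0932) or FFA+TMAO replicate 3 (0.131). The 5 cholangiocyte markers tested did not pass (adjusted p = 0.465). KRT19, a keratin of bile duct cells, had the smallest p among them, at 69.7 ± 9.97 and 85.7 ± 16.0 FPKM, beside EPCAM at 148 ± 7.62 and 144 ± 13.8 and SOX9 at 81.3 ± 9.94 and 85.2 ± 9.84.

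No gene passed the threshold between TMAO-treated cells and cells given FFA alone. Of 10305 genes tested, 0 passed, and the smallest adjusted p was 0.892 (KRT17; limma). At an unadjusted p under 0.05 there were 55 genes, 20 higher and 35 lower with TMAO. That is 0.534% of the genes, where 5% (515 genes) would be counted on average with no effect at all. The values of the groups did not overlap for 317 genes, or 3.08%, where chance gives 10% on average. Genes share the spread between libraries, so a single grouping can fall far from these averages. Every other split of the libraries gave more genes at an unadjusted p under 0.05, 70 to 3902. FFA+TMAO libraries lie at both ends of the first component, which widens the within-group spread. The shortfall is therefore not evidence against an effect. The 95% interval lay within a 1.5-fold change of FPKM + 1 in either direction for 9766 genes (94.8%) and within a 2-fold change for 10243 (99.4%). Here and below, intervals within such a fold are of FPKM + 1. For genes near 1 FPKM they do not bound the change of FPKM itself, which is larger.

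The genes nearest to the threshold were mostly of low expression. KRT17, a keratin of stressed and basal epithelia, stood at 0.681 ± 0.173 FPKM with FFA and 1.84 ± 0.0452 with TMAO, a log2 fold change of 0.76 (95% interval 0.50 to 1.02, unadjusted p = 8.65e-05). TAGLN, an actin-binding protein, stood at 13.5 ± 1.24 and 18.7 ± 1.62, and TMEM249 at 0.619 ± 0.176 and 1.41 ± 0.408. IFI27, an interferon-induced gene, stood at 0.736 ± 0.0858 and 1.499 ± 0.446. On the lower side VIM, the intermediate filament vimentin, stood at 2.06 ± 0.526 and 0.765 ± 0.281 (log2 fold change -0.79, interval -1.15 to -0.44), and SOWAHD at 1.55 ± 0.248 and 0.650 ± 0.124. JAML, a junctional adhesion molecule, stood at 2.45 ± 0.308 and 1.47 ± 0.270, and DEF6 at 7.86 ± 0.820 and 5.62 ± 0.301. None of these passed over all genes. SOWAHD and TMEM249 rested on about 57 and 76 fragments per library.

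The other 2 genes chosen by the smallest p have near-identical copies, so their levels are uncertain. U2AF1, a splicing factor, stood at 1.51 ± 0.448 and 3.41 ± 1.36 FPKM, and its copy U2AF1L5 at 2.28 ± 0.213 and 4.54 ± 3.22. Summed, the pair had a log2 fold change of 0.79, close to that of U2AF1 alone, with 13.1 FPKM in FFA+TMAO replicate 2 against 4.31 to 6.44 in the other TMAO libraries. GTPBP6-2, read here as a second copy of the pseudoautosomal gene GTPBP6 although the sources used here do not explain the suffix, stood at 2.20 ± 1.28 and 0.459 ± 0.379 FPKM, while GTPBP6 itself is listed at 0 in every library. FFA replicate 3 held 3.67 FPKM of GTPBP6-2 and the other FFA libraries 1.44 and 1.47.

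**Figure D1:**
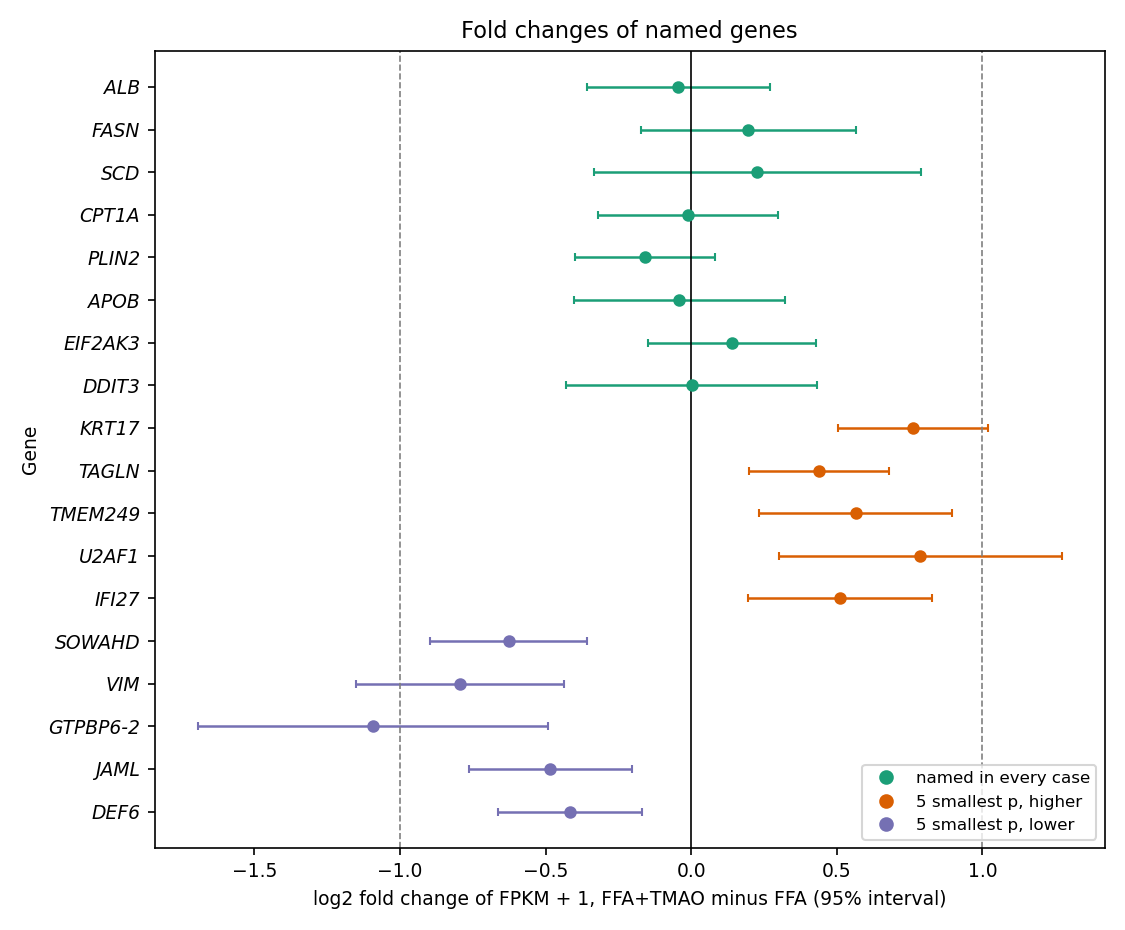
Log2 fold change of FPKM + 1 between FFA+TMAO and FFA (points) with its 95% interval (bars, n = 3 per group) for 8 genes named in every case and the 5 genes with the smallest p in each direction; dashed lines mark a 2-fold change. The intervals of ALB, FASN, SCD, CPT1A, PLIN2, APOB, EIF2AK3 and DDIT3 span 0 and stay within a 2-fold change.

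Genes of cholesterol synthesis and uptake lay higher with TMAO as a group. All 23 tested members had higher mean log2 values, with a median log2 fold change of 0.23, and the list passed (adjusted p = 5.65e-11, camera). With an estimated correlation the adjusted p was 0.688. No member passed over all genes, and 0 passed when adjusted over the list alone. INSIG1, a sterol-induced gene and the list's untested member, is listed near 0 (0.0352 ± 0.0163 and 0.0178 ± 0.0162 FPKM), a doubt about how well these values cover the pathway. MSMO1, a demethylase of the sterol pathway, stood at 26.5 ± 1.11 and 35.2 ± 10.5 FPKM, MVD at 23.6 ± 3.56 and 30.5 ± 7.09, and FDPS at 85.0 ± 3.25 and 102 ± 21.2. FFA+TMAO replicate 2 decided the group's value. MSMO1 was 47.0 FPKM in that library and 31.8 and 26.7 in the other TMAO libraries, beside an FFA range of 25.8 to 27.8. With that library left out the list's median was 0.01 (adjusted p = 0.225).

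Fatty acid and triglyceride synthesis followed the same library. The list passed in the higher direction, with 16 of 18 tested members higher and a median log2 fold change of 0.11 (adjusted p = 0.0105, and p = 0.688 with an estimated correlation). FASN, fatty acid synthase, stood at 103 ± 4.18 and 120 ± 32.0 FPKM, ACLY at 54.0 ± 8.01 and 60.9 ± 10.9, ACSS2 at 14.6 ± 0.298 and 16.7 ± 3.92, ELOVL6 at 3.02 ± 0.255 and 3.40 ± 0.427, and SCD, the stearoyl-CoA desaturase, at 197 ± 38.8 and 240 ± 99.0. None of the 18 passed when adjusted over the list alone. Leaving out FFA+TMAO replicate 2 gave this list a median of -0.05 (adjusted p = 0.225), and without FFA replicate 1 it was 0.07 (adjusted p = 0.169).

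Genes that burn, store and export fat showed no group-wide difference. For fatty acid oxidation and PPAR alpha targets, 11 tested members were higher and 12 lower (adjusted p = 0.792). CPT1A, which admits fatty acids to mitochondria, stood at 12.7 ± 1.00 and 12.7 ± 2.29 FPKM, with an interval of -0.32 to 0.30. FABP1 stood at 2796 ± 161 and 3062 ± 280, ACOT1 at 10.8 ± 0.628 and 12.4 ± 2.59, ETFDH at 5.74 ± 1.34 and 6.41 ± 1.06, and EHHADH at 7.30 ± 1.26 and 8.14 ± 2.00. Among 9 genes of lipid droplets and lipolysis (adjusted p = 0.877), the droplet coat gene PLIN2 stood at 358 ± 4.54 and 322 ± 41.1, an interval of -0.40 to 0.08. CIDEC stood at 4.38 ± 0.182 and 5.27 ± 0.860, HILPDA at 5.43 ± 0.582 and 4.91 ± 0.751, and PLIN3 at 55.2 ± 2.38 and 58.8 ± 5.16. Of 18 apolipoprotein and export genes, 9 were higher and 9 lower (adjusted p = 0.792). APOB, the core protein of exported lipoproteins, stood at 686 ± 143 and 663 ± 94.4, APOA5 at 39.9 ± 4.64 and 36.2 ± 5.37, LIPC at 6.95 ± 0.268 and 7.51 ± 0.0723, SCARB1 at 51.3 ± 4.96 and 48.3 ± 6.76, and APOH at 2167 ± 228 and 2409 ± 614. Mean and median had opposite signs for oxidation (0.02 and -0.01) and for lipid droplets (-0.0099 and 0.05). For the export list both were above 0 (0.0052 and 0.0083) while the test's direction was lower.

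Bile acid, choline and osmolyte genes, fixed for their chemical kinship to TMAO or its known actions, did not pass as groups. CYP7A1, the rate-limiting enzyme of bile acid synthesis, fell under the expression filter, at 0.519 ± 0.223 and 1.38 ± 1.07 FPKM. Its list had 9 of 15 tested members higher (adjusted p = 0.737). SLC51A, a bile acid exporter subunit, stood at 3.87 ± 0.272 and 2.85 ± 0.822 (log2 fold change -0.36, interval -0.73 to 0.0077), NR1H4 at 22.8 ± 1.27 and 24.7 ± 2.35, ACOX2 at 12.1 ± 0.235 and 11.3 ± 1.38, and HSD3B7 at 15.6 ± 1.60 and 16.5 ± 0.827. SLC51A was 1.90 FPKM in FFA+TMAO replicate 2 and 3.30 and 3.34 in the other TMAO libraries. Without that library its log2 fold change was -0.17. Of 16 choline and one-carbon genes, 7 were higher and 9 lower (adjusted p = 0.465), and all 16 intervals lay within a 1.5-fold change. CHKA, choline kinase, stood at 35.6 ± 1.27 and 38.2 ± 1.25, MTR at 4.10 ± 0.509 and 3.62 ± 0.175, SARDH at 13.95 ± 1.00 and 12.9 ± 0.312, and SHMT1 at 20.6 ± 1.84 and 21.8 ± 1.27. Of 7 osmolyte genes, 5 were higher and 2 lower (adjusted p = 0.737), with a median of 0.02 and a mean of -0.01. The taurine transporter SLC6A6 stood at 13.3 ± 2.34 and 12.2 ± 0.725, the myo-inositol transporter SLC5A3 at 7.64 ± 1.93 and 6.80 ± 1.89, SGK1 at 4.36 ± 0.148 and 4.54 ± 0.592, and SLC6A12 at 19.3 ± 3.09 and 22.1 ± 11.3.

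Protein folding genes moved little. The cytosolic heat shock list passed in the higher direction, with 12 of 14 members higher and a median log2 fold change of 0.08 (adjusted p = 0.00162, and p = 0.546 with an estimated correlation). HSPE1, a mitochondrial chaperonin, stood at 97.4 ± 7.05 and 109 ± 4.37 FPKM, HSPA1A at 20.6 ± 1.48 and 22.8 ± 0.839, HSP90AA1 at 183 ± 23.9 and 205 ± 29.05, and HSPH1 at 9.09 ± 1.93 and 10.6 ± 2.28. The endoplasmic reticulum chaperone list passed with 15 of 21 higher and a median of 0.04 (adjusted p = 0.0392, and p = 0.688 with an estimated correlation), and lost the call whichever library was left out (adjusted p = 0.0662 to 0.367). All 21 intervals lay within a 1.5-fold change. EIF2AK3, the PERK kinase proposed as a sensor of TMAO, stood at 7.08 ± 0.669 and 7.94 ± 1.19, with an interval of -0.15 to 0.43. CRELD2 stood at 8.16 ± 0.473 and 10.02 ± 1.86, XBP1 at 301 ± 20.3 and 323 ± 0.357, CALR at 462 ± 24.6 and 502 ± 43.9, and DNAJB11 at 67.8 ± 3.60 and 72.5 ± 1.89.

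Stress programs under ATF4 and NRF2 did not pass. Of 21 tested ATF4 genes, 8 were higher and 13 lower (adjusted p = 0.461). DDIT3, which encodes CHOP, stood at 17.7 ± 3.43 and 17.9 ± 4.61 FPKM, an interval of -0.43 to 0.43. ASNS stood at 37.8 ± 2.58 and 34.8 ± 3.02, TRIB3 at 69.3 ± 3.56 and 74.1 ± 3.34, ATF3 at 6.04 ± 1.35 and 6.83 ± 1.59, and DDIT4 at 76.8 ± 3.76 and 73.3 ± 5.29. NRF2 antioxidant genes were split 10 to 10 (adjusted p = 0.465). AKR1C1 stood at 1220 ± 126 and 1091 ± 158, AKR1C2 at 341 ± 35.4 and 292 ± 90.1, AKR1C3 at 221 ± 23.7 and 199 ± 49.9, and HMOX1 at 21.2 ± 0.112 and 19.9 ± 2.66. The NRF2 list lay higher without FFA+TMAO replicate 2 (median 0.07, adjusted p = 0.00646), and without FFA+TMAO replicate 1 lower (median -0.06, adjusted p = 0.0391). Neither held with an estimated correlation (adjusted p = 0.472 and 0.788).

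The inflammatory genes that could be tested showed no shared direction, while liver acute phase genes passed. The acute phase and complement list had 12 of 18 members higher and a median log2 fold change of 0.06 (adjusted p = 0.0255, and p = 0.688 with an estimated correlation). The fibrinogen chains FGG (353 ± 27.0 and 410 ± 25.8 FPKM), FGB (101 ± 9.69 and 116 ± 8.65) and FGA (225 ± 15.3 and 250 ± 16.0) led it with SAA4, a serum amyloid (0.709 ± 0.233 and 1.34 ± 0.365). None passed when adjusted over the list alone, and SAA4 rested on about 25 fragments per library. Without FFA+TMAO replicate 2 the list's median was 0.18 (adjusted p = 4.20e-10, and p = 0.472 with an estimated correlation). Its call ended without FFA replicate 1 (adjusted p = 0.0767), FFA replicate 2 (0.679), FFA+TMAO replicate 1 (median -0.05, 0.839) or FFA+TMAO replicate 3 (0.150).

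The 13 tested NF-kB and inflammasome genes, of 22 listed, did not pass (9 higher, 4 lower, adjusted p = 0.465). NLRP3, CASP1 (0.612 ± 0.183 and 0.320 ± 0.0528 FPKM), IL1B, IL6, TNF, CCL2, CXCL1, CXCL3 and VCAM1 fell under the filter. The list therefore leaves these inflammasome and cytokine genes untested. IL18 stood at 1.84 ± 0.699 and 2.32 ± 0.652 FPKM, the chemokine CCL20 at 693 ± 59.4 and 613 ± 208, BIRC3 at 1.45 ± 0.192 and 1.63 ± 0.130, and NFKBIA at 106 ± 0.705 and 112 ± 5.70. This list lay higher without FFA+TMAO replicate 2 (median 0.07, adjusted p = 0.00646) or FFA replicate 3 (median 0.09, adjusted p = 0.00146). With an estimated correlation the adjusted p of these was 0.472 and 0.538. Interferon genes were 8 higher and 5 lower (adjusted p = 0.410), with IFITM1 at 3.01 ± 1.06 and 2.04 ± 1.06, IRF1 at 2.07 ± 0.0237 and 2.53 ± 0.594, and IRF9 at 9.83 ± 0.427 and 10.9 ± 1.31 beside IFI27. Immediate early genes, fixed as a check of RNA quality, passed in the lower direction, with 13 of 14 lower and a median of -0.12 (adjusted p = 0.00251, and p = 0.688 with an estimated correlation). MYC stood at 73.5 ± 4.27 and 65.3 ± 12.7, FOSL1 at 5.54 ± 0.385 and 4.99 ± 0.456, EGR1 at 38.4 ± 4.39 and 35.3 ± 1.87, and IER2 at 62.6 ± 12.9 and 56.0 ± 9.38. Without FFA+TMAO replicate 2 that median was 0.05 (adjusted p = 0.302), and without FFA replicate 1 it was -0.06 (adjusted p = 0.148).

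Glycolysis and hypoxia-response genes lay lower with TMAO as a group. All 23 tested members had lower mean log2 values, with a median log2 fold change of -0.21 (adjusted p = 5.65e-11, camera). With an estimated correlation the adjusted p was 0.688, and 0 members passed when adjusted over the list alone. BNIP3, a mitophagy receptor induced by hypoxia, stood at 105 ± 3.39 and 89.7 ± 15.7 FPKM, VEGFA at 66.9 ± 4.90 and 58.8 ± 9.69, the glucose transporter SLC2A1 at 109 ± 11.1 and 94.4 ± 17.3, and ANKRD37 at 8.45 ± 0.935 and 6.50 ± 3.35. FFA+TMAO replicate 2 again stood apart: ANKRD37 was 2.99 FPKM there and 6.85 to 9.67 in the other 5 libraries. Without that library the list's median was 0.0077 (adjusted p = 0.919), while with array weights, which rest on replicate 3 of each group, it was -0.16 (adjusted p = 0.00103, and p = 0.967 with an estimated correlation). Gluconeogenesis and insulin signalling passed in the lower direction, with 6 of 10 lower and a median of -0.09 (adjusted p = 0.0255, and p = 0.688 with an estimated correlation). PCK1, the gluconeogenic carboxykinase, stood at 7.88 ± 0.548 and 6.45 ± 0.478, G6PC1 at 2.38 ± 0.316 and 1.94 ± 0.227, GCKR at 11.9 ± 0.899 and 13.2 ± 1.34, and PCK2 at 111 ± 7.96 and 98.9 ± 20.8. That call ended without FFA+TMAO replicate 2 (median -0.0019, adjusted p = 0.609), FFA replicate 1 (0.0606) or FFA replicate 2 (0.170).

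**Figure D2:**
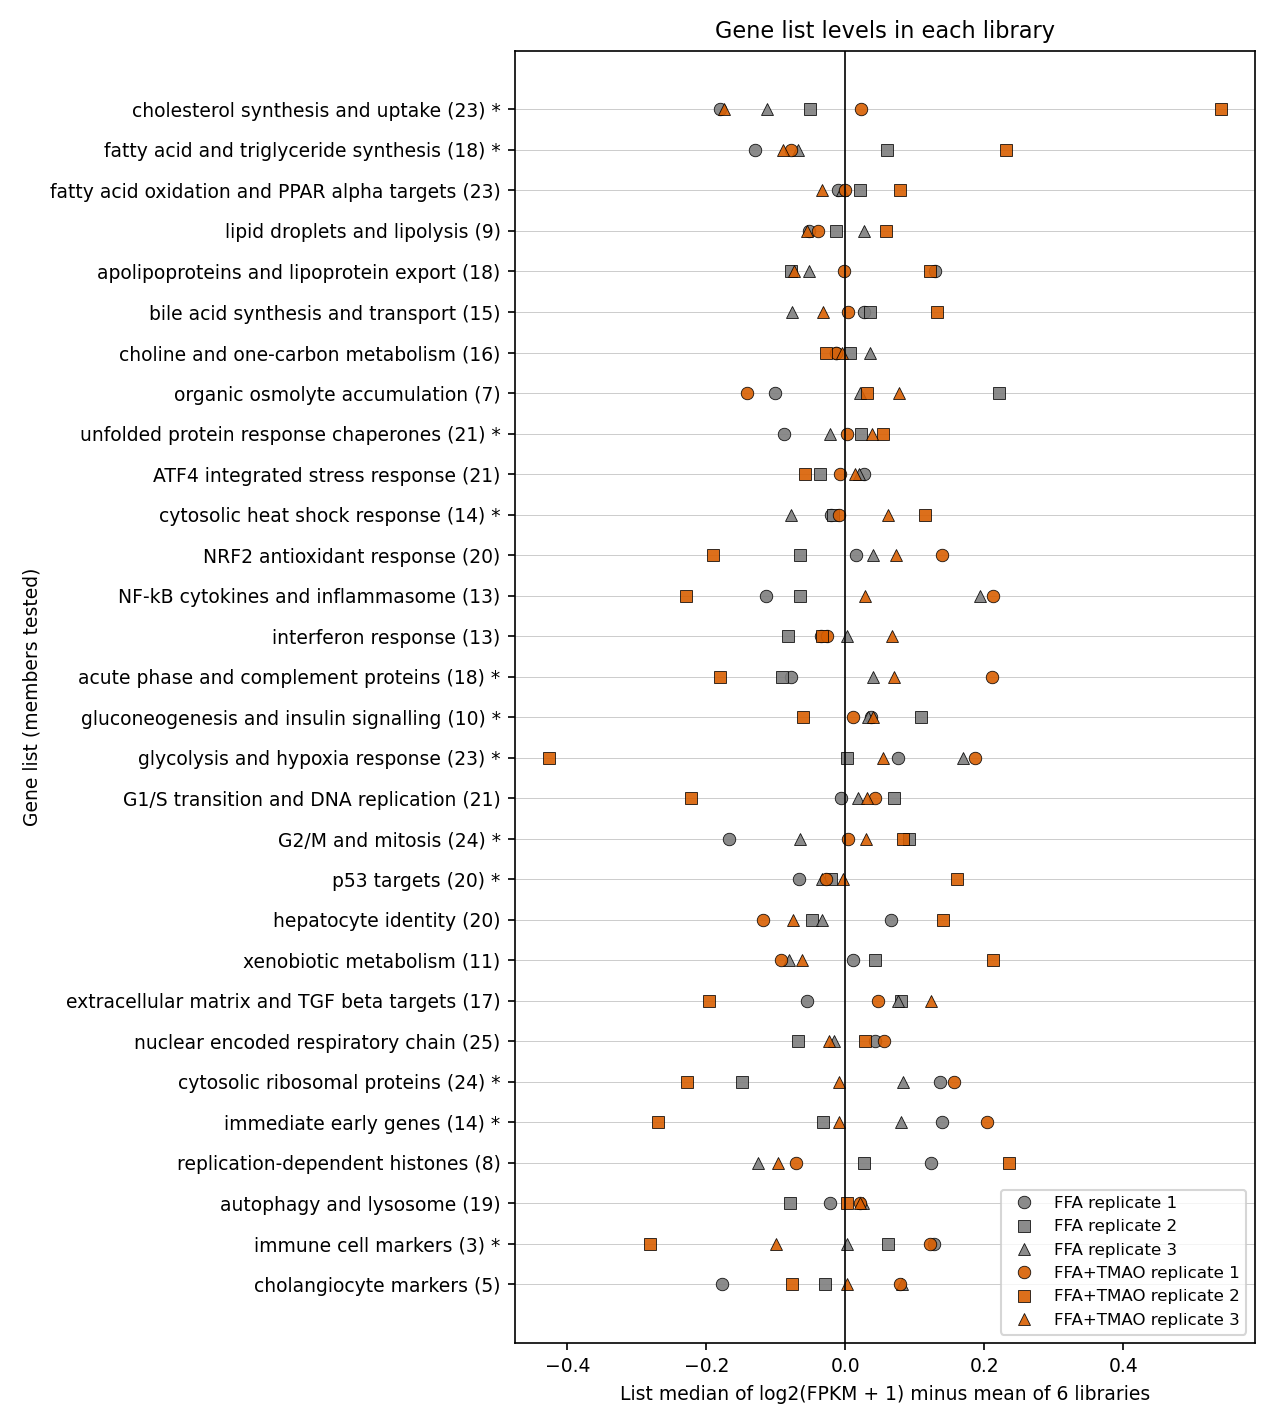
Median over each list's tested members of log2(FPKM + 1) after subtraction of each gene's mean over the 6 libraries, by library (grey FFA, orange FFA+TMAO; circle, square and triangle for replicates 1 to 3); the number of tested members is in brackets and * marks lists past the threshold with the preset correlation. FFA+TMAO replicate 2 stands at 0.54 for cholesterol synthesis and uptake and at -0.43 for glycolysis and hypoxia, where the other 5 libraries lie between -0.18 and 0.19.

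Cell cycle and p53 lists differed by small amounts. Mitotic genes passed in the higher direction, with 19 of 24 higher, a median log2 fold change of 0.04 and all 24 intervals within a 1.5-fold change (adjusted p = 0.00409, and p = 0.688 with an estimated correlation). AURKA, a mitotic kinase, stood at 28.0 ± 2.24 and 32.5 ± 3.33 FPKM, CCNB1 at 36.9 ± 4.45 and 42.3 ± 3.17, CENPA at 12.9 ± 2.42 and 15.2 ± 1.04, and BIRC5 at 37.8 ± 0.211 and 41.8 ± 4.57. The call ended without FFA replicate 1 (adjusted p = 0.518), FFA+TMAO replicate 1 (0.0591) or FFA+TMAO replicate 2 (0.0628). Replication genes did not pass (6 higher, 15 lower, adjusted p = 0.144), with CDC45 at 7.19 ± 0.306 and 6.36 ± 0.825, MCM2 at 32.7 ± 1.54 and 29.6 ± 3.40, PCNA at 159 ± 9.30 and 171 ± 3.01, and TYMS at 67.3 ± 4.84 and 72.2 ± 2.04. They did pass in the lower direction without FFA+TMAO replicate 1 (median -0.08, adjusted p = 0.0132) or FFA+TMAO replicate 3 (median -0.09, adjusted p = 0.0172), and after quantile normalization (median -0.05, adjusted p = 0.0474). None of these held with an estimated correlation (adjusted p = 0.788, 0.644 and 0.728). Targets of p53 passed in the higher direction, with 18 of 20 higher and a median of 0.08 (adjusted p = 0.00162, and p = 0.688 with an estimated correlation). The cell cycle inhibitor CDKN1A stood at 43.3 ± 3.78 and 54.7 ± 12.1, FAS at 0.930 ± 0.0898 and 1.17 ± 0.200, GADD45A at 45.4 ± 2.90 and 49.7 ± 2.48, and PHLDA3 at 20.1 ± 1.72 and 23.9 ± 5.76. That list's median was 0.02 without FFA+TMAO replicate 2 (adjusted p = 0.188).

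Ribosomal protein genes, also fixed as a check of RNA quality, passed in the lower direction, with 24 of 24 lower and a median log2 fold change of -0.05 (adjusted p = 0.0289, and p = 0.809 with an estimated correlation). RPL23 stood at 415 ± 33.8 and 392 ± 56.9 FPKM, RPS27 at 1265 ± 96.7 and 1208 ± 124, RPL13 at 344 ± 53.1 and 323 ± 61.1, and RPL10 at 576 ± 52.6 and 552 ± 68.2. The direction turned without FFA+TMAO replicate 2, to a median of 0.06 (adjusted p = 0.0271, and p = 0.641 with an estimated correlation), and the call ended without FFA replicate 1 (0.564) or FFA replicate 3 (0.562). Nuclear genes of the respiratory chain were 16 higher and 9 lower (adjusted p = 0.109), all 25 with intervals within a 1.5-fold change. SDHC stood at 57.4 ± 5.85 and 65.1 ± 5.13, NDUFV2 at 76.3 ± 2.00 and 83.3 ± 1.203, SDHA at 46.1 ± 1.16 and 49.3 ± 1.72, and NDUFA1 at 113 ± 10.1 and 121 ± 4.30. They passed in the higher direction without FFA replicate 1 (median 0.04, adjusted p = 0.00689) or FFA+TMAO replicate 3 (median 0.05, adjusted p = 0.0436). Neither call held with an estimated correlation (adjusted p = 0.779 and 0.644).

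Extracellular matrix and TGF beta targets did not pass as a list (9 higher, 8 lower, adjusted p = 0.465), with a median log2 fold change of 0.0056 and a mean of -0.06. VIM was its single member past the threshold when adjusted over the list alone (adjusted p = 0.0120, limma), and it did not pass over all genes. TIMP1 stood at 20.2 ± 1.58 and 24.9 ± 5.95 FPKM and the fibronectin gene FN1 at 1578 ± 140 and 1401 ± 261. Without FFA+TMAO replicate 2 the list lay higher (median 0.09, adjusted p = 0.0412, and p = 0.472 with an estimated correlation). Xenobiotic metabolism genes were 5 higher and 6 lower (adjusted p = 0.410), with a median of -0.0094 and a mean of 0.05. CYP1A1, a target of the aryl hydrocarbon receptor, stood at 3.30 ± 0.399 and 4.12 ± 0.583, TIPARP at 2.26 ± 0.318 and 2.76 ± 0.158, UGT2B7 at 12.5 ± 2.04 and 14.6 ± 5.54, and ABCB1 at 15.0 ± 3.37 and 17.2 ± 6.02. Autophagy and lysosome genes (13 higher, 6 lower, adjusted p = 0.410) all had intervals within a 1.5-fold change, with NPC2 at 118 ± 6.19 and 133 ± 14.8, LAMP1 at 128 ± 1.13 and 135 ± 9.49, GABARAPL1 at 16.1 ± 1.80 and 14.7 ± 4.06, and LIPA at 36.3 ± 5.98 and 40.7 ± 12.3. Replication-dependent histones were 5 higher and 3 lower (adjusted p = 0.443), with H2AC6 at 5.13 ± 1.12 and 6.95 ± 2.80, H2BC8 at 0.952 ± 0.217 and 1.12 ± 0.119, H2BC5 at 1.98 ± 0.5005 and 2.41 ± 0.872, and H2BC4 at 0.943 ± 0.360 and 1.19 ± 0.610.

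In all, 12 of the 30 lists passed with the preset correlation, 7 higher and 5 lower. The lower ones include ribosomal proteins and immediate early genes, which were fixed as checks of RNA quality. With camera and an estimated correlation 0 passed (smallest adjusted p = 0.546), and with fry 0 passed (smallest adjusted p = 0.951). Estimated correlations between members were 0.545 for the cholesterol list, 0.807 for glycolysis and 0.971 for ribosomal proteins, against the preset 0.01. Among the 12, only heat shock (0.0059) and gluconeogenesis (-0.014) lay under the preset. Both lost the call as well (adjusted p = 0.546 and 0.688, camera with an estimated correlation), so shared movement is not the only reason. That form takes its p from the few residual degrees of freedom, so a list's failure under it decides little. Members of the rest of the 12 moved together, so their preset p-values overstate the evidence. Of the 12, the heat shock list alone kept its call and direction whichever library was left out. Estimated array weights were the single alternative under which any gene passed, 2778 of them. That estimation did not converge, and it gave FFA replicate 3 and FFA+TMAO replicate 3 weights of 6.84 and 7.23 against 0.251 to 0.830 for the others.

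The libraries differed from each other across the groups. The first principal component held 61.1% of the variance and had FFA+TMAO libraries at both ends, replicate 1 at -14.5 and replicate 2 at 22.1, and the groups did not separate on it (exact permutation p = 0.7). On component 3, with 7.81% of the variance, all FFA+TMAO scores (1.82 to 6.26) lay above all FFA scores (-8.23 to 0.70). Its exact permutation p was 0.1, the smallest possible, and that of components 2, 4 and 5 was 0.7, 0.2 and 0.7. Pearson correlations of log2 values were 0.979 to 0.996 within groups and 0.982 to 0.997 between them.

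**Figure D3:**
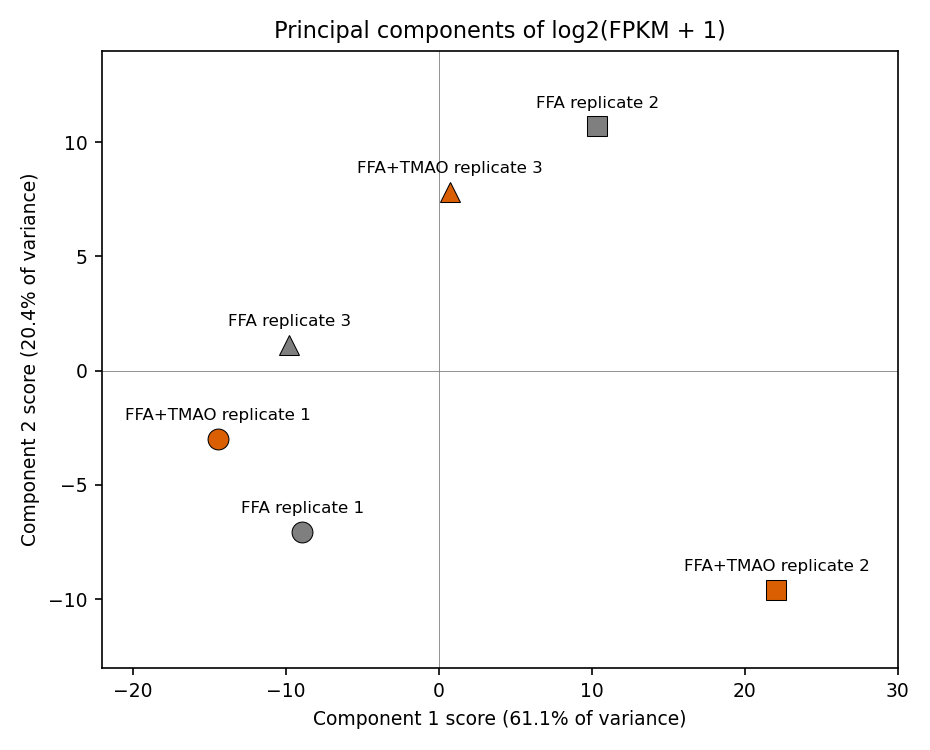
Scores of the 6 libraries on the first and second principal components of log2(FPKM + 1) (grey FFA, orange FFA+TMAO; axes in score units with the percent of variance held). On the first component FFA+TMAO replicate 2 lies at 22.1 and FFA replicate 2 at 10.4, while FFA+TMAO replicate 1 lies at -14.5.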

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

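Of the alternatives run, the GC and length correction, the residual component and the gene-by-gene array weights were chosen after seeing the data. The count of 0 genes held in 19 of 20 alternative fits, with a smallest adjusted p of 0.0731 among them, and in each fit that left out a library (0 to 0 genes in all, higher and lower). Under array weights the genes past the threshold were 2778, the genes higher with TMAO 1592 and the genes lower with TMAO 1186, from an estimation that did not converge; weights estimated gene by gene gave 0. An unadjusted p under 0.05 with at least a 1.5-fold change gave 7 genes, 2 higher and 5 lower. For gene lists, 6 passed without a filter (among them the stellate cell and fibroblast markers, lower), 2 with array weights (glycolysis and ribosomal proteins, lower), 5 with gene-by-gene weights, 5 to 11 with a library left out (5 without FFA replicate 1 and 7 without FFA+TMAO replicate 2), and 0 with an estimated correlation or fry. Under array weights the log2 fold change of APOB was 0.23 and that of H2BC4 was -0.35, both past the threshold against the sign given above. The list median log2 fold change of cytosolic ribosomal proteins went from -0.14 without FFA+TMAO replicate 1 to 0.057 without FFA+TMAO replicate 2, past the threshold in both. The cause was not tested, except that the weights rest on FFA replicate 3 and FFA+TMAO replicate 3. Among the other values, named genes stayed uncalled and within the within-group SD of their main value in 2554 cases, moved further in 49 and passed in 47. Lists kept call and direction, or stayed uncalled within that spread, in 503. They lost the call in 62, gained it in 11 and moved in 22. Signs were not compared where neither fit passed, so a value near 0 could change side and still count as unmoved.

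With the replicate number as a replicate block, 0 genes and 10 lists passed, and genes at an unadjusted p under 0.05 went from 55 to 213. Same-numbered libraries deviated together by r = 0.448, 0.512 and 0.065 across genes, and 3 of the 6 libraries correlated best with their own number, so the numbers were not taken to pair the samples. The GC and length correction gave 123 genes at an unadjusted p under 0.05 and the residual component 394, with 0 past the threshold. Depth was near equal and limits low genes only.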

Other observations

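The tests of sequencing depth, of treatment on the first component, of the gene count after the GC correction and of leaving out FFA+TMAO replicate 2 were chosen after their results were seen. Genes named in the next paragraph were also chosen after their values were seen, from those with the largest loadings on the first component.

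FFA+TMAO replicate 2 lay far from the other 5 libraries in several genes with large loadings on the first component. HAMP, the iron hormone hepcidin, was 1.76 FPKM there and 15.3 to 32.8 elsewhere. IGFBP1, an insulin-repressed binding protein, was 48.1 against 297 to 448, LCN2 was 2.93 against 20.7 to 43.4, and CA9, a carbonic anhydrase induced by hypoxia, was 0.666 against 6.73 to 12.5. In the other direction HMGCS1, a synthase of the mevalonate route, was 38.15 against 12.4 to 17.4, and DIO1, a thyroid hormone deiodinase, was 31.1 against 8.66 to 13.96. These are values of a single library and have no replicate. In cells given the same label, FFA+TMAO replicate 1 held 32.8 FPKM of HAMP and 448 of IGFBP1.

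The real grouping gave 0 genes past the threshold, and with a count of 0 all 10 splits of the 6 libraries give as many or more by construction, so this comparison decides nothing. With 10 splits no share under 0.05 can be had in any case. The highest other split gave 1719 genes, between FFA replicates 1 and 3 with FFA+TMAO replicate 1 on one side and FFA replicate 2 with FFA+TMAO replicates 2 and 3 on the other. The remaining splits gave 0 or 1 genes, so a count of 0 was the usual outcome. The large count, picked as the highest, belongs to the split along the first component and restates that structure, which does not follow the treatment.

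For the first component, which sets the same 3 libraries below 0, depth is argued against as the source, since the libraries at its ends had recovered depths within 1.0004 times of each other, and so is TMAO, with TMAO libraries at both ends (exact permutation p = 0.7). Across genes, which are not independent replicates, the loading correlated with GC content (Spearman -0.516) and log transcript length (0.433), and a correction for both took the split from 1719 genes to 0 past the threshold, while 1859 genes had an unadjusted p under 0.05. The median absolute log2 fold change of the 1719 genes fell from 0.34 to 0.17 and their median SE from 0.081 to 0.072, so the calls ended because the differences shrank; a library-preparation effect tied to GC content or length may account for part of those differences. The same correction left the first component at 61.4% of the variance (61.1% before) and FFA+TMAO replicate 2 at 22.6 on it. Other libraries moved: FFA replicate 1 from -8.93 to -4.085, FFA replicate 2 from 10.4 to 3.52 and FFA+TMAO replicate 3 from 0.74 to -3.32. The corrected component thus mainly set FFA+TMAO replicate 2 apart. The glycolysis and hypoxia list stayed at a median of -0.4413 in FFA+TMAO replicate 2, so GC content and length are not the whole source. Before the correction 17 HIF targets outside that list lay at -0.1818 there, 16 of them below their means, and after it at -0.22; a culture state with less hypoxia signalling in that library's cells is a hypothesis for that part.

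The higher cholesterol list under TMAO may come from FFA+TMAO replicate 2 alone, since without it the list's median log2 fold change was 0.0124 instead of 0.23. Leaving the library out also ended the call of the lower glycolysis list (median 0.0077); array weights left that list at -0.16 and gene-by-gene weights at -0.15, but both rest mostly on FFA+TMAO replicate 3 and FFA replicate 3 (7.23 and 6.84, not converged, and 2.42 and 3.05), so they decide neither list. The GC and length correction left the cholesterol list at 0.2302, which argues against that bias. A shared effect of TMAO stays open, with an exact permutation p of 0.3 for the cholesterol list's mean per library, where 0.1 is the smallest possible. Over the 6 libraries the medians of the 2 lists had r = -0.879 (exact permutation p = 0.126) and rho = -0.257 (exact permutation p = 0.658), and r = -0.255 without the 2 libraries farthest from the median, so this relation, the single one across libraries computed, rests on those libraries.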
